A study of Homo sapiens with 16 samples.

How the data were processed

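Polyadenylated RNA from HL60 cells was extracted with TRIzol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The deposited gene table holds whole-number read counts, made by the authors with featureCounts 1.6.2 with strand setting 1, per the file headers. The labels do not say whether the kit kept strand, so reads of overlapping antisense genes may not be separable. Each of the 18093 rows is a RefSeq transcript counted over 1 interval from its start to its end, introns included, per the file headers, so that reads of unspliced RNA count as well. Rows that overlap others on the same strand can lose shared reads, and 444 rows had 0 counts in every library. The genome build is GRCh38, per the submitters' processing notes, which also name DESeq2, and 99.63% of the rows whose symbol has a place in the reference on that build overlapped it. The table has 8 count columns, 1 for each numbered replicate, and columns not used numbered 0. How the 2 technical repeats of a replicate entered a column was not given in the sources used here.

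The second deposited file is a table of the authors' own comparison, whose values (expected inclusion from 0 to 1, its difference, and a posterior probability) carry the column names of MAJIQ and Voila output, per the file headers. No version was given in the sources used here. The authors' difference is control minus SY-351, checked against both inclusion columns (the sign matched in 100% of entries that differed by at least 0.05), and was turned to SY-351 minus control. Of the variations, 11.8% lay on their own gene's place in GENCODE v29 on GRCh38, so the table uses another build. No splicing coordinate is printed for that reason. Its folder name carries the words no outliers, and which samples were left out was not given in the sources used here.

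Transcript identifiers were matched to gene symbols through a RefSeq gene table (17867 rows) and GENCODE (134 rows), and 92 rows kept their identifier. Where 2 rows shared a symbol the one with the higher total was used, which set aside 15. Of 3700 genes with a splicing variation, 3395 were matched to a symbol by Ensembl identifier or name. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, robust glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p below 0.05), with group as the only term and all 8 libraries. Gene lists were tested with camera of limma 3.58.1 on log CPM at an inter-gene correlation preset to 0.01, adjusted over the 31 lists with at least 5 tested genes. With an estimated correlation 0 of the lists passed (smallest adjusted p = 0.221). SE is the log2 fold divided by the square root of the F statistic, and CPM are TMM-scaled. The 32 lists, the tests and the rule for named genes were fixed before the data were examined. The list of mitochondrially encoded mRNAs has 0 rows in the table.

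The rule named, among genes past the threshold with a mean of at least 10 CPM and no overlap between groups, the 8 largest folds in each direction, leaving out LOC, LINC and MIR symbols. It further named the 3 members with the smallest adjusted p of each list past camera, the 2 members with the highest CPM of every other list, and always CDK7, CCNH, MNAT1, MYC, MYB, MCL1, RUNX1, E2F1, HEXIM1 and POLR2A. For splicing it named the 10 genes with the largest difference past a probability of 0.95, and up to 3 members of each list of splicing, 3' end or transcription machinery. Members of lists that are only counted are left out of the text, and 1 further gene that the rule named is not reported here. Introns and exons were counted once each, with exact binomial tests against an even split. The overlap of expression and splicing used Fisher's exact test and the Mantel-Haenszel odds ratio with its chi-square test over deciles of mean log CPM (SciPy 1.17.1, statsmodels 0.14.6). That mean was taken over all 8 libraries.

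The pipeline was tested on simulated counts drawn from the real means, library sizes and spread. With the spread of all 8 libraries 0 of 100 genes changed 2-fold and 0 of 100 changed 4-fold were recovered, with 0 of 14976 unchanged genes called. Both simulated groups were given the spread fitted over all 8 libraries, which includes the wide spread of the DMSO group. The real SY-351 libraries varied less than the DMSO group. The simulation therefore does not set the limit of the real fit, which called 2550 genes. With DMSO 3 and 4 only, 79% of genes changed 2-fold and 97% changed 4-fold were recovered, and 22 of 15361 unchanged genes were called. On a made splicing table all 400 events were recovered in their direction, and an odds ratio made at 3 over 8000 genes was found as 2.71 within deciles and 4.85 without them.

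Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, other size factors, total count scaling, other filters, a 1.5-fold threshold, a replicate block, leaving out each library, other set tests and other probability thresholds. Scaling to mitochondrial mRNAs was not run for want of rows. Fits without DMSO 1 and 2 or without DMSO 3 and 4 were added after seeing the data. Transcript GC content and length came from GENCODE v29 for 97.6% of rows. Replicate libraries of a group differed by more than sampling noise in every pair (chi-square per degree of freedom of at least 12.5), so no pair was treated as 1 library deposited again, which does not show that they came from separate cultures. Depth of 43.3 to 124.2 M counts per library means that spread between libraries, not counting error, limits the precision of most genes, while for genes near 3 counts, such as H4C3 and H4C4 in DMSO, counting error limits it as well.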

Results

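The steady-state polyadenylated RNA of HL60 cells, a human acute promyelocytic leukaemia line, was sequenced after 5 h in 50 nM SY-351, an inhibitor of the kinase CDK7, or in the solvent DMSO. CDK7 is the catalytic subunit of the CDK-activating kinase, a part of the general transcription factor TFIIH. The study asked what CDK7 does in gene expression, in splicing and in termination. Each group held 4 numbered replicates, and each replicate was listed with 2 technical repeats, so that 16 records stood behind 8 count columns. Nothing in the labels said that the replicates came from separate cultures, so p-values measure only the spread between these samples. Counts assigned to genes totalled 107.3, 103.7, 124.2 and 116.8 M in DMSO replicates 1 to 4, and 77.9, 77.7, 61.4 and 43.3 M in SY-351 replicates 1 to 4. At these totals 3 counts equalled 0.0241 to 0.0693 CPM, counts scaled to the library total. The CPM of genes given below are also TMM-scaled, so this level is only approximate for them. The second file was a table of local splicing variations comparing SY-351 with control, without values per sample.

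DMSO replicates 1 and 2 stood apart from every other library. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.994 between DMSO 1 and 2 and 0.993 between DMSO 3 and 4, but 0.782 to 0.807 between these pairs. DMSO 3 and 4 had r of 0.95 to 0.961 with the SY-351 libraries, which had r of 0.994 to 0.999 with each other. EEF1A1, the translation elongation factor, measured 118 and 101 CPM in DMSO 1 and 2 against 5690 and 8650 CPM in DMSO 3 and 4 and 16400 to 18400 CPM with SY-351. The ferritin light chain FTL measured 36.5 and 17.6 CPM in DMSO 1 and 2, 2610 and 3630 CPM in DMSO 3 and 4, and 9140 to 9790 CPM with SY-351. Both genes were chosen after their values were seen. The mean GC content of the most GC-rich 600 nt of each transcript, weighted by counts, was 66.1 and 66.3% in DMSO 1 and 2, 60.4 and 60.3% in DMSO 3 and 4, and 59.81 to 59.95% in the SY-351 libraries. All tests below use all 8 libraries as fixed in advance. Counts and folds without DMSO 1 and 2, a choice made after seeing the data, are given beside them. They cover the lists that passed, several other lists and most named genes.

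**Figure D1:**
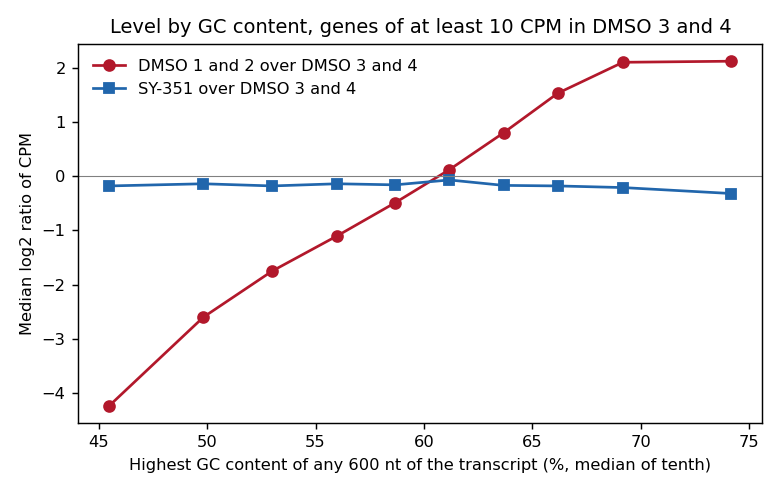
Median log2 ratio of CPM (y axis) in deciles of genes ordered by the highest GC content of any 600 nt of the transcript (x axis, %), for genes of at least 10 CPM in DMSO 3 and 4. The ratio of DMSO 1 and 2 to DMSO 3 and 4 runs from -4.23 in the lowest decile to 2.12 in the highest, while that of SY-351 to DMSO 3 and 4 stays between -0.32 and -0.07.

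The first comparison asked which mRNAs differed after CDK7 inhibition. MYC, the proto-oncogene transcription factor (chromosome 8, 127736230 to 127742951, GRCh38), fell from 3670 ± 2760 CPM (SD, n = 4) in DMSO to 121 ± 11 CPM (SD, n = 4) with SY-351. Its log2 fold was -4.93 ± 0.74 (SE, adjusted p = 0.00699, edgeR quasi-likelihood test), and -3.38 ± 0.16 (SE, adjusted p = 8.15e-97) without DMSO 1 and 2. Of 31 lists of genes fixed in advance, 11 passed camera towards lower and 4 towards higher levels, and 0 of these passed with an estimated correlation (adjusted p of 0.221 to 0.593). No added RNA standard was counted, so only relative levels were measured. With DMSO 1 and 2 as the only controls, also chosen after seeing the data, 7 of the 15 lists no longer passed camera. Of 15472 genes tested, 450 were higher and 2100 lower with SY-351 at an edgeR adjusted p below 0.05, and 401 and 2042 of these changed at least 2-fold. In 2821 genes all 4 SY-351 libraries lay below all 4 DMSO libraries and in 2392 genes above them, 33.7% of genes. Chance would give 2.86% if all 8 libraries were exchangeable. They were not, since DMSO 1 and 2 stood apart from DMSO 3 and 4, so the 33.7% cannot be read as an excess over chance.

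Without DMSO 1 and 2, 3466 genes were higher and 4172 lower of 15811 tested, and 431 and 2056 of the calls with 8 libraries were among them, with 0 opposite calls. Total count scaling without these libraries moved the median log2 fold of all genes to -0.45 and gave 2065 higher and 6848 lower, so that the lower share of calls was 76.8% in place of 54.6%. With 8 libraries that share was 82.4%, and 92% under total count scaling. Leaving out a single SY-351 library gave 66, 68, 61 and 76 higher and 473, 602, 487 and 602 lower genes, for replicates 1 to 4. Leaving out DMSO 1, 2, 3 or 4 gave 196, 246, 1885 and 674 higher and 1264, 1458, 3438 and 2500 lower genes.

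Among genes of at least 10 CPM without overlap between the groups, the 8 that fell furthest were CHAC1, CILP2, WNT6, FAM110A, LRFN1, SAC3D1, CPTP and PIM1. CHAC1, a glutathione-degrading enzyme induced by the integrated stress response, measured 58.9 ± 51 CPM (SD, n = 4) in DMSO and 0.63 ± 0.258 CPM (SD, n = 4) with SY-351, a log2 fold of -6.55 ± 0.92 (SE, edgeR adjusted p = 0.00562). PIM1, a serine/threonine kinase proto-oncogene, had a log2 fold of -5.70 ± 0.74 (SE, edgeR adjusted p = 0.00446). The log2 folds of CILP2, WNT6, FAM110A, LRFN1, SAC3D1 and CPTP lay between -6.54 and -5.71. All 8 were higher in DMSO 1 and 2 than in DMSO 3 and 4, and without DMSO 1 and 2 their log2 folds lay between -4.58 for CHAC1 and -3.03 for CPTP. Without DMSO 2 alone the log2 folds of FAM110A and SAC3D1 were -5.48 and -5.17 in place of -6.12 and -5.77. The edgeR calls of CPTP and LRFN1 ended without SY-351 replicate 1 (adjusted p = 0.0518 and 0.0504), and those of CPTP and FAM110A without SY-351 replicate 3 (adjusted p = 0.0511 and 0.0512).

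The 8 that rose furthest were HFM1, SLCO5A1, KCNJ2, IRF4, EML6, TECRL, KCTD16 and LRRIQ1. KCNJ2, an inward rectifier potassium channel (chromosome 17, 70169534 to 70180042, GRCh38), measured 4.43 ± 4.9 CPM (SD, n = 4) in DMSO and 230 ± 30 CPM (SD, n = 4) with SY-351, a log2 fold of 5.69 ± 1.28 (SE, edgeR adjusted p = 0.022). IRF4, a lymphoid and myeloid transcription factor, measured 3 ± 3.27 CPM (SD, n = 4) and 144 ± 19 CPM (SD, n = 4), a log2 fold of 5.58 ± 1.31 (SE, edgeR adjusted p = 0.0251). The KCNJ2 and IRF4 calls ended when any single SY-351 library was left out (adjusted p up to 0.0657 and 0.0724), that of IRF4 also under total count scaling (adjusted p = 0.0539), and without DMSO 1 and 2 their log2 folds were 4.76 ± 0.21 and 4.65 ± 0.21 (SE, adjusted p = 1.89e-112 and 1.07e-106). The log2 fold of KCNJ2 was 6.45 without DMSO 4 alone. EML6, TECRL, KCTD16 and LRRIQ1 had log2 folds of 4.96, 4.90, 4.67 and 3.94, and 4.46, 4.13, 3.95 and 3.32 without DMSO 1 and 2. That of LRRIQ1 was 4.56 without DMSO 3 alone. HFM1 and SLCO5A1 rested on SY-351 replicate 4, at 10000 and 12300 CPM against 268 to 319 and 206 to 273 CPM in the other 3 SY-351 libraries. When that library was left out both stayed called, with log2 folds of 3.92 and 3.05 in place of 7.17 and 6.88. Both calls ended when DMSO 1 or 2 or SY-351 1, 2 or 3 was left out, and that of SLCO5A1 also without DMSO 4 (edgeR adjusted p up to 0.071 and 0.0823). With DMSO 1 and 2 both left out neither passed, at edgeR adjusted p of 0.164 and 0.18.

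Of 33 immediate early genes tested, which respond to growth factor signals without new protein synthesis, 19 were lower and 0 higher, or 25 lower adjusted over the list alone (camera adjusted p = 1.23e-08; adjusted p = 0.41 with an estimated correlation). DUSP5 and DUSP6, phosphatases of the MAP kinases, had log2 folds of -3.43 ± 0.33 and -3.81 ± 0.53 (SE, edgeR adjusted p = 0.00288 and 0.00524). CSRNP1 had a log2 fold of -2.96 ± 0.34 (SE, edgeR adjusted p = 0.00312). NF-kB and inflammatory genes were lower in 10 of 20 and higher in 0, or 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000817; adjusted p = 0.221 with an estimated correlation). NFKBIA, the NF-kB inhibitor, had a log2 fold of -3.14 ± 0.46, NFKB2 of -4.25 ± 0.67 and CD83 of -2.71 ± 0.43 (SE, edgeR adjusted p = 0.00634, 0.00753 and 0.00755). Against DMSO 3 and 4 alone, 20 immediate early genes were lower and 5 higher, and 16 NF-kB genes were lower and 1 higher. The median log2 fold of the immediate early list was then -0.75, in place of -2.73 with 8 libraries. That of the NF-kB list was -1.83 in place of -2. In that comparison the log2 folds of DUSP5, DUSP6, CSRNP1, NFKBIA, NFKB2 and CD83 were -3.08, -2.72, -2.53, -2.31, -2.66 and -3.08. The NF-kB list did not pass camera with DMSO 1 and 2 as the only controls (adjusted p = 0.151), with 12 of 21 lower and 5 higher.

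Of 40 myeloid transcription factors tested, 19 were lower and 0 higher, or 22 lower adjusted over the list alone (camera adjusted p = 6.57e-06; adjusted p = 0.351 with an estimated correlation). NFE2, a haematopoietic leucine zipper factor, had a log2 fold of -2.92 ± 0.28 and the interferon regulatory factor IRF1 of -3.11 ± 0.44 (SE, edgeR adjusted p = 0.00288 and 0.00568). MYB had a log2 fold of -0.95 ± 0.27 (SE, edgeR adjusted p = 0.0448), a call that ended when any library but DMSO 3 was left out (adjusted p up to 0.164), with other size factors, with total count scaling and with no filter (adjusted p = 0.0551, 0.0927 and 0.0717). RUNX1 did not pass the test, with a log2 fold of -1.31 ± 0.57 (SE, edgeR adjusted p = 0.157), and 0.12 ± 0.16 without DMSO 1 and 2. It passed without DMSO 3, at -1.57 (edgeR adjusted p = 0.0399). Of the 40 factors 21 were lower and 1 higher against DMSO 3 and 4 alone, with log2 folds of -2.67 for NFE2, -2.25 for IRF1 and -0.90 for MYB.

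Of 49 E2F targets of G1/S and DNA replication, 16 were lower and 1 higher, or 21 and 2 adjusted over the list alone (camera adjusted p = 0.000197; adjusted p = 0.221 with an estimated correlation). CDC25A, a phosphatase that activates CDK2, had a log2 fold of -3.40 ± 0.33, the flap endonuclease FEN1 of -2.52 ± 0.24 and the replication factor GINS3 of -3.01 ± 0.31 (SE, edgeR adjusted p = 0.00288 for each). E2F1 itself had a log2 fold of -3.11 ± 0.49 (SE, edgeR adjusted p = 0.00743). Of 40 G2/M genes, 13 were lower and 0 higher, or 14 lower adjusted over the list alone (camera adjusted p = 0.0311; adjusted p = 0.593 with an estimated correlation). The mitotic kinase PLK1 had a log2 fold of -3.83 ± 0.53, CCNA2 of -3.33 ± 0.47 and the spindle motor KIF11 of -1.74 ± 0.24 (SE, edgeR adjusted p = 0.00517, 0.00565 and 0.00499). Against DMSO 3 and 4 alone, 37 E2F targets were lower and 5 higher, and 36 G2/M genes were lower and 3 higher. There the log2 folds of CDC25A, FEN1, GINS3, E2F1, PLK1, CCNA2 and KIF11 were -2.93, -2.57, -3.11, -2.05, -2.70, -2.38 and -1.81. With DMSO 1 and 2 as the only controls, 28 E2F targets were lower and 17 higher, and 18 G2/M genes were lower and 21 higher, with a G2/M median log2 fold of 0.67. Neither list passed camera in that comparison (adjusted p = 0.165 and 0.7). The G2/M list no longer passed camera when DMSO 3 or DMSO 4 was left out.

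Ribosome biogenesis factors were lower in 13 of 37 and higher in 0, or 18 lower adjusted over the list alone (camera adjusted p = 0.00575; adjusted p = 0.352 with an estimated correlation). URB2, BYSL and NOB1 had log2 folds of -2.29 ± 0.24, -3.56 ± 0.40 and -2.53 ± 0.30 (SE, edgeR adjusted p = 0.00291, 0.00304 and 0.00324). Of these factors 27 were lower and 1 higher without DMSO 1 and 2; leaving out DMSO 4 alone ended the camera call. For URB2, BYSL and NOB1 the log2 folds without DMSO 1 and 2 were -2.24, -2.86 and -2.15. Of the factors 19 were lower and 16 higher with DMSO 1 and 2 as the only controls (camera adjusted p = 0.769). Cytosolic ribosomal protein genes went the other way as a list (camera adjusted p = 1.58e-09; adjusted p = 0.342 with an estimated correlation). They took 7.38 ± 0.7% of counts (SD, n = 4) in DMSO and 15.7 ± 0.21% (SD, n = 4) with SY-351. With 8 libraries 3 of 68 were higher, RPL10A, RPS19 and RPL35, with log2 folds of 1.34 ± 0.33, 1.58 ± 0.39 and 1.92 ± 0.55 (SE, edgeR adjusted p = 0.0286, 0.0307 and 0.0464), and 0 adjusted over the list alone. These 3 calls ended when DMSO 1 or any single SY-351 library was left out, those of RPL10A and RPS19 also without DMSO 2 (adjusted p up to 0.124), and with DESeq2 size factors (edgeR adjusted p = 0.0693, 0.061 and 0.0579). The RPL35 call also ended with total count scaling and with no filter (adjusted p = 0.0925 and 0.0535). All 68 were higher without DMSO 1 and 2, with a median log2 fold of 1.42 and log2 folds of 1.36, 1.58 and 1.66 for RPL10A, RPS19 and RPL35. With DMSO 1 and 2 as the only controls, 53 of the 68 were higher and 12 lower, with a median log2 fold of 6.21. The small SD of the share of counts in DMSO therefore does not mean that the members had alike levels in the 4 DMSO libraries.

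Genes of the integrated stress response and the unfolded protein response were lower in 13 of 28 and higher in 0, or 16 lower adjusted over the list alone (camera adjusted p = 1.52e-05; adjusted p = 0.221 with an estimated correlation). XBP1, a transcription factor of the unfolded protein response, fell from 616 ± 410 CPM (SD, n = 4) to 18.3 ± 1.61 CPM (SD, n = 4), a log2 fold of -5.07 ± 0.61 (SE, edgeR adjusted p = 0.00334). HERPUD1 and DNAJB9, which act in endoplasmic reticulum protein quality control, had log2 folds of -4.94 ± 0.63 and -3.69 ± 0.41 (SE, edgeR adjusted p = 0.00425 and 0.00291). Of 22 cholesterol synthesis and uptake genes, 5 were lower and 0 higher, also 5 adjusted over the list alone (camera adjusted p = 0.0361; adjusted p = 0.221 with an estimated correlation). SQLE and MVK, enzymes of cholesterol synthesis, had log2 folds of -4.08 ± 0.45 and -3.81 ± 0.50 (SE, edgeR adjusted p = 0.00291 and 0.00465). Against DMSO 3 and 4 alone, 18 stress genes were lower and 2 higher, and 14 cholesterol genes were lower and 3 higher. The log2 folds of XBP1, HERPUD1, DNAJB9, SQLE and MVK were there -3.88, -3.59, -3.04, -3.25 and -2.73. The cholesterol list did not pass with DMSO 1 and 2 as the only controls (camera adjusted p = 0.468), with 11 lower and 8 higher. The cholesterol list no longer passed camera when DMSO 3 or DMSO 4 was left out.

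Of 17 BCL2 family genes, 5 were lower and 0 higher, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00488; adjusted p = 0.41 with an estimated correlation). Among 27 p53 target genes 10 were lower and 0 higher, also 10 adjusted over the list alone (camera adjusted p = 0.00575; adjusted p = 0.408 with an estimated correlation). Both camera calls ended without DMSO 1 and 2 (adjusted p = 0.205 and 0.0673), where 7 BCL2 family genes were lower and 1 higher, and 14 p53 targets lower and 2 higher. The anti-apoptotic gene MCL1 measured 208 ± 128 CPM (SD, n = 4) and 78 ± 3.59 CPM (SD, n = 4), a log2 fold of -1.41 ± 0.48 that did not pass the test (SE, edgeR adjusted p = 0.079), and -0.32 ± 0.16 without DMSO 1 and 2. It passed under total count scaling, with DESeq2 and without DMSO 3 (adjusted p = 0.0132, 0.0176 and 0.0187).

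Replication-dependent histone genes, whose mRNAs normally end in a stem-loop without a poly(A) tail, were higher in 10 of 33 and lower in 0, or 14 higher adjusted over the list alone (camera adjusted p = 4.1e-07; adjusted p = 0.41 with an estimated correlation). All 33 were highest in replicate 4 among the SY-351 libraries, 27 of them at least 2-fold above each of the other 3, against 29.8% highest there among all tested genes, a count chosen after the values were seen. H1-4 and H1-5, also chosen after their values were seen, measured 20.6 and 11.7 CPM in replicate 4 and at most 1.59 and 1.17 CPM in the others, and neither passed the test (edgeR adjusted p = 0.11 and 0.0788). Without SY-351 replicate 4 the list still passed camera (adjusted p = 6.35e-07; adjusted p = 0.31 with an estimated correlation), with 6 higher in place of 10 and a median log2 fold of 1.14 in place of 2.21. Without SY-351 1, 2 or 3 there were 4, 6 and 5 higher. H2BC21 measured 1.79 ± 0.204 CPM (SD, n = 4) in DMSO and 8.36 ± 2.51 CPM (SD, n = 4) with SY-351, a log2 fold of 2.22 ± 0.32 (SE, edgeR adjusted p = 0.00585). H4C3 and H4C4 lay near or under the approximate level of 3 counts in DMSO, at 0.0481 and 0.0212 CPM, and at 4.69 and 0.91 CPM with SY-351. Those SY-351 means rested in part on replicate 4, at 9.8 CPM against 2.74 to 3.19 CPM in the other 3 for H4C3, and at 2.34 CPM against 0.252 to 0.617 CPM for H4C4. Both calls stayed when it was left out (edgeR adjusted p = 0.0273 and 0.0352). Histone genes have near-identical copies, so how the counting split their reads is uncertain. Of 31 tested without DMSO 1 and 2, 20 were higher and 0 lower, with SY-351 replicate 4 included, and the log2 fold of H2BC21 was 2.33. With DMSO 1 and 2 as the only controls 11 of 33 were higher and 1 lower (camera adjusted p = 0.253).

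Primary granule genes passed as a list towards higher levels (camera adjusted p = 0.0123; adjusted p = 0.221 with an estimated correlation), although 0 of 10 passed alone, also 0 adjusted over the list alone. PRG2, the major basic protein of eosinophil granules, LYZ (lysozyme) and CTSG (cathepsin G) had log2 folds of 1.45 ± 0.43, 2.18 ± 0.66 and 2.05 ± 0.72 (SE, edgeR adjusted p = 0.0527, 0.0566 and 0.0886). DESeq2 called all 3 higher (adjusted p = 0.00192, 0.00124 and 0.0119). Of the 10 genes 9 were higher and 0 lower without DMSO 1 and 2, with log2 folds of 1.79, 1.53 and 1.34 for PRG2, LYZ and CTSG. Leaving out DMSO 3 alone ended the camera call, as did DMSO 1 and 2 as the only controls (camera adjusted p = 0.221; 7 higher, 3 lower). Neutrophil and monocyte maturation genes were higher in 5 of 28 and lower in 2, the same counts as adjusted over the list alone (camera adjusted p = 0.00437; adjusted p = 0.221 with an estimated correlation). Lactoferrin (LTF) and the integrin subunits ITGAX and ITGAM had log2 folds of 3.16 ± 0.36, 2.06 ± 0.25 and 1.90 ± 0.28 (SE, edgeR adjusted p = 0.00315, 0.00334 and 0.00621). Against DMSO 3 and 4 alone, 16 of the 28 were higher and 7 lower, with log2 folds of 2.76, 2.00 and 2.25 for LTF, ITGAX and ITGAM. Lymphoid markers passed camera towards higher levels in that comparison too (adjusted p = 0.0327; adjusted p = 0.644 with an estimated correlation), with 5 of 14 higher and 1 lower.

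Transcriptional CDKs, cyclins and their regulators were lower in 5 of 17 and higher in 0, also 5 adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.474 with an estimated correlation), a call that ended without DMSO 1 and 2 (camera adjusted p = 0.264; 8 lower, 2 higher) and when DMSO 2 or DMSO 4 alone was left out. MEPCE and HEXIM2, which bind the 7SK RNA that holds P-TEFb inactive, had log2 folds of -3.25 ± 0.55 and -3.00 ± 0.62, and the Mediator kinase CDK8 of -1.81 ± 0.46 (SE, edgeR adjusted p = 0.00872, 0.0162 and 0.0333). Without DMSO 1 and 2 these were -1.99 ± 0.15, -1.55 ± 0.31 and -0.77 ± 0.16 (SE, edgeR adjusted p = 2.82e-36, 2.43e-06 and 3.29e-06). The HEXIM2 and CDK8 calls ended when any single SY-351 library was left out (adjusted p up to 0.0717 and 0.11), that of CDK8 also without DMSO 1, without DMSO 2 and with limma-voom (adjusted p = 0.0789, 0.0685 and 0.0571). HEXIM1, the CDK7 partner CCNH and the assembly factor MNAT1 did not pass the test, with log2 folds of -0.82 ± 0.47, -0.21 ± 0.81 and 0.82 ± 0.89 (SE, edgeR adjusted p = 0.27, 0.872 and 0.554). CCNH was lower without DMSO 1 and 2, at -1.07 ± 0.17 (SE, edgeR adjusted p = 8.68e-10), while HEXIM1 and MNAT1 changed sign and did not pass, at 0.30 ± 0.16 and -0.07 ± 0.16 (SE, edgeR adjusted p = 0.113 and 0.774). The expression of CDK7 and POLR2A was not analysed here.

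The other 16 lists did not pass camera with 8 libraries, with adjusted p of at least 0.0584. Lower members numbered 0 of 7 in the CDK-activating kinase and TFIIH, 0 of 11 RNA polymerase II subunits, 5 of 26 Mediator subunits, 4 of 41 core spliceosome components, 3 of 39 SR proteins, hnRNPs and CLK kinases and 3 of 32 factors of 3' end processing and termination, with 0 higher in each. DNA repair genes were lower in 5 of 36, heat shock genes in 5 of 16, glycolysis genes in 4 of 22, and snoRNA hosts and NMD-sensitive transcripts in 1 of 9, with 0 higher in each. Nuclear oxidative phosphorylation genes were higher in 2 and lower in 2 of 35, interferon-stimulated genes higher in 1 and lower in 2 of 27, and zinc finger genes named ZNF higher in 5 and lower in 93 of 480. Of markers of other cell types, 2 of 8 erythroid genes were lower, 1 of 14 lymphoid genes was higher, and 0 of 11 epithelial and fibroblast genes passed. Adjusted over the list alone, the lower counts became 2 for 3' end factors and 0 for snoRNA hosts, ZNF genes 6 higher and 97 lower, and oxidative phosphorylation and lymphoid genes 0 in both directions, with the other lists as given. For RNA polymerase II subunits the median log2 fold was -0.25 and the mean 0.01, and for glycolysis genes 0.38 and -0.06. Against DMSO 3 and 4 alone more members were called. RNA polymerase II subunits were higher in 6 and lower in 3, CDK-activating kinase and TFIIH in 1 and 3, and core spliceosome components in 7 and 16. SR proteins, hnRNPs and CLK kinases were higher in 12 and lower in 14, DNA repair genes in 4 and 19, and glycolysis genes in 10 and 8. None of these lists passed camera there (adjusted p of at least 0.0511).

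**Figure D2:**
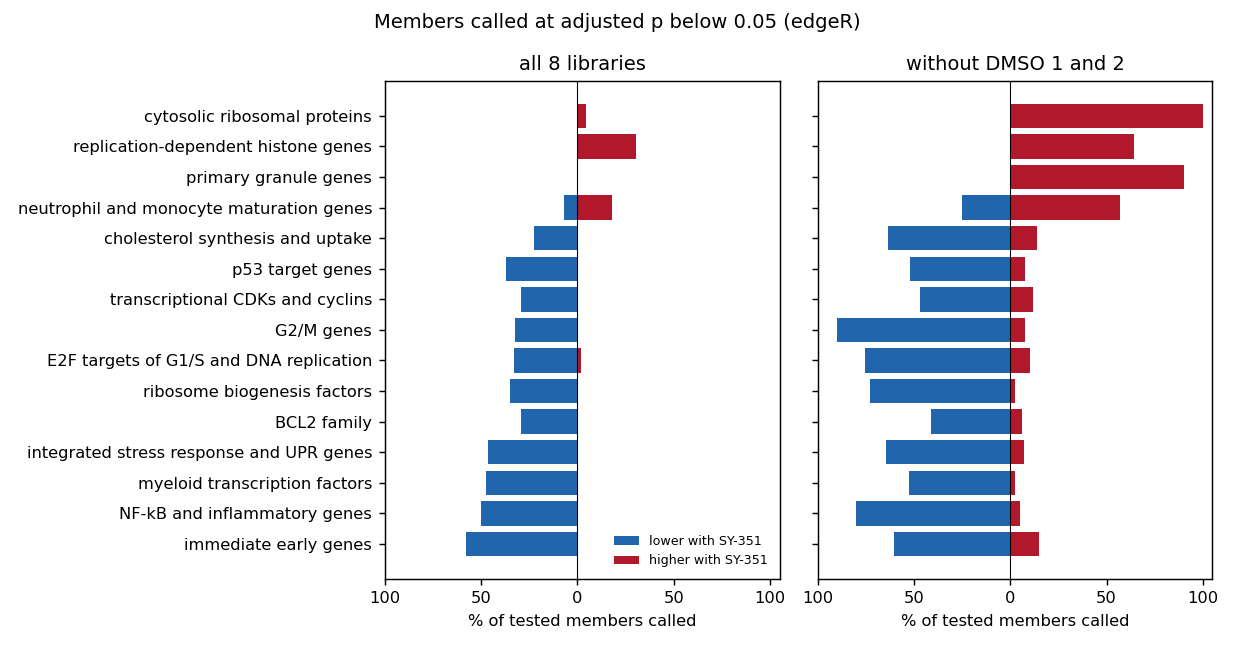
Share of tested members (x axis, %) called lower (blue, to the left) or higher (red, to the right) with SY-351 at an edgeR adjusted p below 0.05, for the 15 lists past camera with all 8 libraries. The left panel uses all 8 libraries and the right panel leaves out DMSO 1 and 2; all 68 ribosomal protein genes are higher in the right panel against 3 in the left.

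**Figure D3:**
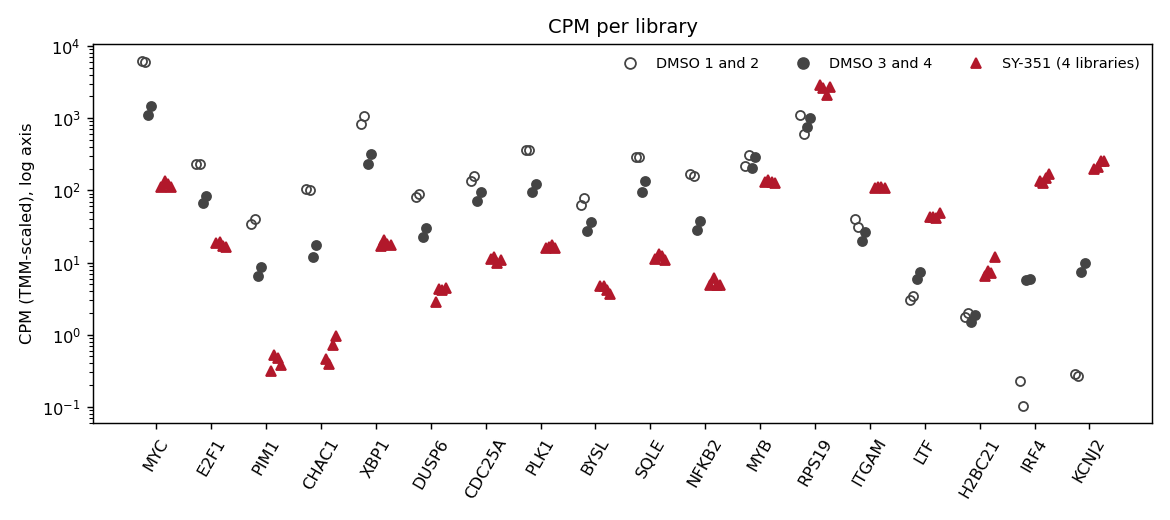
TMM-scaled CPM per library (log axis) of 18 named genes, with DMSO 1 and 2 as open circles, DMSO 3 and 4 as filled circles and the 4 SY-351 libraries as triangles. For MYC the DMSO libraries lie at 6140, 5980, 1100 and 1460 CPM and the SY-351 libraries between 111 and 135 CPM.

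The second comparison asked how splicing differed, from the authors' deposited table of local splicing variations, each a set of junctions, with or without a retained intron, that start or end at the same exon. Inclusion is the expected share of a variation's reads that use a given junction or intron, from 0 to 1. The table listed 6716 variations in 3700 genes, and in every one of them inclusion differed by at least 0.2 summed over one direction, so it lists changed variations and not all that were measured. In 3738 variations of 2375 genes the authors' probability of a difference of at least 0.2 reached 0.95, and with 0.90 and 0.99 as thresholds there were 4326 and 2885. Which samples entered the comparison was not given in the sources used here, and the table's link column names a folder without outliers.

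Introns were retained less often with SY-351 in most changed cases. Of 354 introns past a probability of 0.95 in the authors' deposited table, 100 were retained more and 254 less (exact two-sided binomial test, p = 1.39e-16; introns are not replicates). Over the variations holding them, median inclusion went from 0.748 in control to 0.206 with SY-351 where retention fell, and from 0.184 to 0.643 where it rose. Whether DMSO 1 and 2, which were relatively low in transcripts of low GC content, were among the controls is not known. An effect of that on intron inclusion was not tested. Cassette exons showed no excess in either direction. Of 418 exons in 2-way exon skipping variations of the authors' deposited table, 195 were less and 223 more included with SY-351 (exact two-sided binomial test, p = 0.187; exons are not replicates). Among variations without a de novo junction, a choice made after seeing the data, 77 exons of the authors' deposited table were less and 109 more included (exact two-sided binomial test, p = 0.0228).

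Unannotated junctions gained use with SY-351. Of the 3738 changed variations of the authors' deposited table, 3206 held a junction marked as de novo, that is, absent from the annotation the authors used. Of all variations listed there 84.8% held one, so that count does not set the changed ones apart. Of the de novo junctions past a probability of 0.95, 1254 were used more and 159 less with SY-351, against 1617 and 3260 of the annotated junctions. In the 3173 changed variations with both kinds, the summed inclusion of de novo junctions rose in 2592 and fell in 581, with a median of 0.031 in control and 0.324 with SY-351. This count was chosen after the table was seen.

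The 10 genes with the largest differences in the authors' deposited table included 5 in which a retained intron was lost. Intron inclusion fell from 0.986 to 0.013 in ENOSF1, from 0.995 to 0.032 in TRIM59, from 0.98 to 0.001 in the cold shock protein gene YBX3, from 0.954 to 0.004 in MTREX, an RNA helicase of the nuclear exosome, and from 0.952 to 0.002 in the ubiquitin ligase gene COP1. A de novo junction went from 0.015 to 0.972 in GNRH1, from 0.022 to 0.975 in EPS15L1 and from 0.03 to 0.985 in SLC36A1. An annotated junction went from 0.978 to 0.011 in RP11-231C14.9 and from 0.98 to 0.046 in WFIKKN1. The authors' probability was 1 to 3 decimals in all 10.

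Of all tested genes 12.9% held a changed variation in the authors' deposited table, against 1 of 7 (14.3%) in the CDK-activating kinase and TFIIH, 2 of 17 (11.8%) transcriptional CDKs and cyclins, 1 of 11 (9.1%) RNA polymerase II subunits and 8 of 26 (30.8%) Mediator subunits. Within deciles of expression none of these 4 shares passed a test against other genes (Mantel-Haenszel chi-square test, adjusted p of at least 0.265). CDK7 and GTF2H4, without counts in the gene table, are not among the 7. In the authors' deposited table the most changed junction, an annotated one, went from 0.917 to 0.45 in CDK7, from 0.939 to 0.516 in MNAT1 and from 0.817 to 0.531 in GTF2H4, a TFIIH subunit. Annotated junctions likewise went from 0.893 to 0.072 in CCNL2 and from 0.81 to 0.396 in CCNL1, cyclins of the splicing-associated CDK11, and a de novo junction from 0.039 to 0.879 in POLR2B, the second largest subunit of RNA polymerase II. In Mediator the annotated junctions of MED23, MED4 and MED13 fell from 0.975 to 0.527, from 0.786 to 0.337 and from 0.955 to 0.542.

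Of the 39 tested SR protein, hnRNP and CLK kinase genes, 22 (56.4%) held a changed variation in the authors' deposited table. The shares were 3 of 41 (7.3%) for core spliceosome components and 7 of 32 (21.9%) for factors of 3' end processing, against the 12.9% of all tested genes. U2AF1, without counts in the gene table, is not among the 41. Intron inclusion fell from 0.859 to 0.037 in HNRNPD and from 0.834 to 0.166 in HNRNPDL, and an annotated junction from 0.964 to 0.246 in SON. Among core components an annotated junction went from 0.16 to 0.662 in PRPF3, from 0.998 to 0.48 in AQR and from 0.939 to 0.513 in U2AF1. Among 3' end factors SCAF4, a suppressor of early polyadenylation, went from 0.997 to 0.234, CLP1 from 0.979 to 0.401 and FIP1L1 from 0.596 to 0.198.

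**Figure D4:**
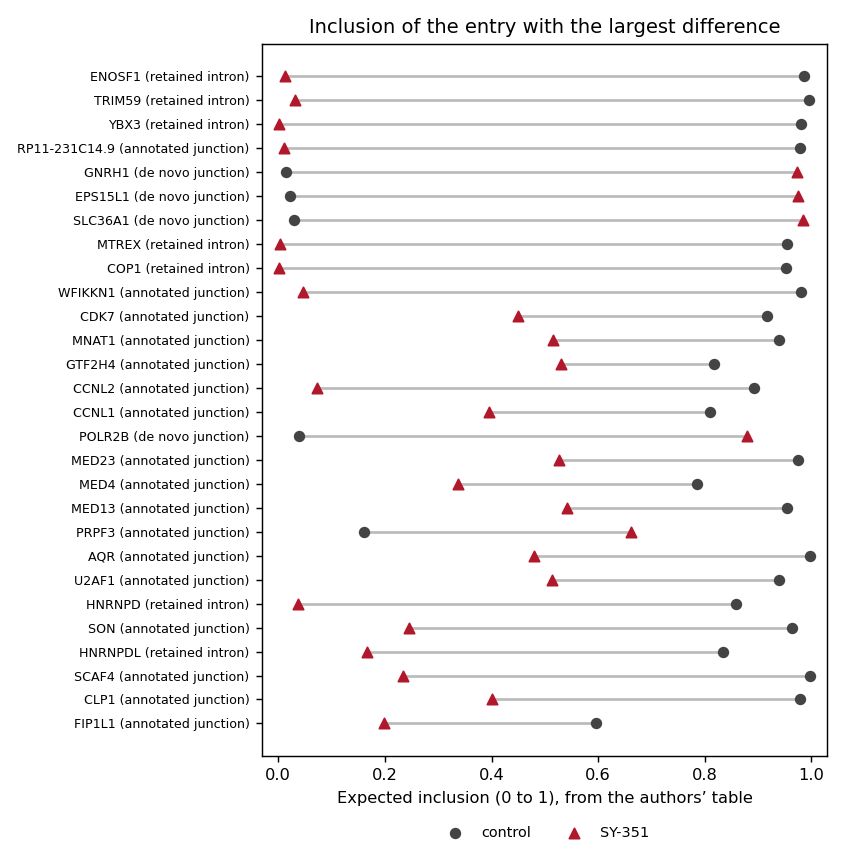
Expected inclusion (x axis, 0 to 1) in control (circles) and with SY-351 (triangles) of the intron or junction with the largest difference in each named gene, as given in the authors' deposited table, with no error per sample. In ENOSF1 the retained intron goes from 0.986 in control to 0.013 with SY-351.

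The third comparison asked whether the same genes changed in expression and in splicing. Of the 2550 genes called in expression 422 (16.5%) held a changed variation, against 12.2% of the other tested genes and 328.5 expected by chance (Fisher's exact test, two-sided, odds ratio 1.43, p = 4.44e-09). Within deciles of mean expression the Mantel-Haenszel odds ratio was 0.95 (95% interval 0.842 to 1.07, chi-square test, p = 0.407), and 0.889 (95% interval 0.802 to 0.986, chi-square test, p = 0.0264) for DESeq2 calls. Genes are not replicates. Genes higher with SY-351 held changed variations less often than other genes, 7.8% against 13%, with a Mantel-Haenszel odds ratio of 0.561 (95% interval 0.393 to 0.801, chi-square test, p = 0.00122). Genes lower with SY-351 held them in 18.4% against 12%, with a Mantel-Haenszel odds ratio of 1.03 (95% interval 0.912 to 1.17, chi-square test, p = 0.606). Against DMSO 3 and 4 alone the Mantel-Haenszel odds ratios were 0.575 (95% interval 0.508 to 0.65) for higher and 1.59 (95% interval 1.44 to 1.76) for lower genes. The deciles there still used the mean over all 8 libraries. As the splicing table lists changed variations only, all 15472 tested genes served as background.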

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

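All tests of explanations in this part were chosen after the result was seen, except the splits of the samples. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes as the real one, which was the real one itself. It called 2550 genes by edgeR at an adjusted p below 0.05, and the highest of the other splits called 0. A share of 1 in 35 is the smallest that these splits can give. Chance is argued against to that degree, provided that the libraries are independent.

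The search for single libraries far from the other 3 of their group covered 134 groups of values, in the library measures and in 62 named genes. It found 7, all in SY-351 genes, where chance alone would give 6.7 over all 134 groups. That number counts the DMSO groups, in which DMSO 1 and 2 often lay apart from DMSO 3 and 4, so that a single far library could hardly be found. It therefore does not tell whether the SY-351 values exceed chance. HFM1 and SLCO5A1 were far higher in SY-351 replicate 4, with gaps of 0.995 and 0.994 of the group's range. H4C3 measured 9.8 CPM in the same library against 2.74 to 3.19 CPM in the others, a gap of 0.936. In SY-351 replicate 1, DUSP6 measured 2.82 CPM against 4.19 to 4.39 CPM (0.873) and IRF1 5.31 CPM against 4.89 to 4.95 CPM (0.857). In SY-351 replicate 2, HERPUD1 measured 5.91 CPM against 4.3 to 4.49 CPM (0.882) and NFKB2 6.11 CPM against 4.85 to 4.87 CPM (0.984). SY-351 replicate 4 held 16 genes of at least 10 CPM at 10 times or more the level of each other SY-351 library, 2.86% of its counts, among them the histone genes H1-4 and H1-5, and replicates 1, 2 and 3 held 2, 0 and 0 such genes. All 33 tested replication-dependent histone genes were highest in SY-351 replicate 4 of that group.

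DMSO 1 and 2 stood apart from DMSO 3 and 4. Sequencing depth is argued against, since the smaller of their totals was 2.4 times the lowest SY-351 total. Of the 50 genes with the highest CPM in DMSO 3 and 4, 19 lay at least 8-fold lower in DMSO 1 and 2, against 2 in SY-351. EEF1A1 and FTL, which human cells in general express, were among the 19. RNA of another cell type or a swapped sample is therefore argued against as the only cause. Whether either was present together with another loss cannot be told from these values. A loss of transcripts of low GC content may account for the split, as the log2 ratio of DMSO 1 and 2 to DMSO 3 and 4 had a Spearman rho of 0.7 with GC content across 8079 genes, against -0.03 for SY-351 over DMSO 3 and 4. The step that caused it was not tested, and no biological explanation was tested because the labels give both pairs the same treatment.

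The list of cytosolic ribosomal protein genes passed camera towards higher levels with SY-351 (adjusted p = 1.58e-09; adjusted p = 0.342 with an estimated correlation), with 3 of 68 called higher with 8 libraries. Under total count scaling without DMSO 1 and 2 the median log2 fold of the list was 1.0. That scaling shifted genes in general, moving the median of all genes to -0.45. It shows only that the rise does not rest on the choice between these 2 scalings, which both give relative levels. DMSO 1 and 2 as the cause are argued against by the 68 genes called higher without them. Short and abundant transcripts rose in general. The median log2 fold was 1.0 in 10000 random lists matched on transcript length and on mean expression over all 8 libraries. The ribosomal protein median of 1.42 lay at percentile 100 of them, so such a trend may carry a part. Ribosomal protein genes moved together (estimated correlation 0.766 without DMSO 1 and 2), which random lists do not keep. The percentile therefore does not settle whether the trend carries the whole rise of the ribosomal protein genes. An effect of SY-351 on their relative levels stays open as a hypothesis, and neither RNA stability nor absolute levels were measured.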

How the results depend on the processing

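The fits without DMSO 1 and 2 or without DMSO 3 and 4, and the intron and exon shares without de novo junctions, were chosen after seeing the data; the cause of each shift below was not tested unless stated. Against 450 higher and 2100 lower genes, total count scaling gave 215 higher (lower within 1.5 times), DESeq2 1064 and 3484, and a 1.5-fold threshold 151 and 1320. DMSO 3 and 4 only gave 3466 and 4172, or 3320 and 4008 with DESeq2, 2065 and 6848 with total count scaling and 1466 and 2488 (62.9% lower) with a 1.5-fold threshold; DMSO 1 and 2 only gave 6372 and 5996, and 2434 of its calls were opposite to those with DMSO 3 and 4 only. Leaving out 1 library gave 61 to 1885 higher and 473 to 3438 lower genes, the lowest with a SY-351 library out and the highest with DMSO 3 out. DESeq2's size factors moved the median of all genes to -0.11 and limma-voom to 0.23.

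Adding the replicate block gave 0 and 0 genes with edgeR, with 3649 at an unadjusted p below 0.05 and 14 lists past camera, 13 of them among the 15 without it. G2/M and cholesterol genes no longer passed (camera adjusted p = 0.0601 and 0.0526), and oxidative phosphorylation genes did (camera adjusted p = 0.0363). With the block and an estimated correlation 0 lists passed camera (smallest adjusted p = 0.437). Whether the numbers pair the samples cannot be told. Deviations of same-numbered libraries from their group means correlated at 0.01, -0.05, 0.02 and -0.12, and not every library correlated best with its own number. In DMSO those deviations mostly held the split of DMSO 1 and 2 from DMSO 3 and 4, which could hide a pairing. Of 15 lists past camera 0 passed with an estimated correlation, 16 lists passed fry, 9 camera with DMSO 1 and 2 only, and 11 to 17 with 1 library left out. Over all genes, leaving out 1 SY-351 library gave 539 to 678 calls in place of 2550. Most named genes were picked for a small adjusted p or a large fold, so their share does not stand for all calls. Of 54 named genes called, 41 stayed called whichever library was left out, and 0 changed sign. In the other 6 planned settings but the block 45 stayed called in each and 6 did not, while 3 had no value in 1 setting and stayed called in the rest (HFM1 and SLCO5A1, without an adjusted p from DESeq2, and H4C4, not tested at a mean of at least 1 CPM); the 1.5-fold threshold was run for counts of genes only. Against 3738 changed variations, 6647 differed by at least 0.2 in a single junction or intron whatever the probability, and 532 of the changed ones held no de novo junction. The share of introns retained more (28.2%) ranged from 28.9 to 32% with other probabilities, and was 24.8% without de novo junctions, past the threshold in each. The overlap's odds ratio of 1.43 was 1.40 with a probability of 0.90 and 1.31 with DESeq2 calls, past the threshold in both, but 0.95, 0.914 and 0.889 within deciles of expression; requiring 1.5-fold removed 0 of its 2550 genes, so that setting tests nothing. The share of exons less included (46.7%) stayed short of the threshold with other probabilities (46.4 to 48.5%) and passed it at 41.4% without de novo junctions (p = 0.0228, exact binomial test). Scaling to mitochondrial mRNAs was not run. Folds of 2 or 4 were not detected in simulated genes when both groups were given the spread of all 8 libraries. The real SY-351 libraries varied less than the DMSO group, and the real fit called genes such as KIF11, 3.35-fold lower (edgeR adjusted p = 0.00499). The simulation therefore does not set the limit of the real fit.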

Other observations

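The tests of lists without DMSO 1 and 2, the splicing counts per list and the test of downstream genes were chosen after seeing the data, and the tests of unannotated junctions were written before their results were seen. Without DMSO 1 and 2, 6 further lists passed camera. Mediator subunits were lower in 15 and higher in 3 of 26 (adjusted p = 0.00363), heat shock genes lower in 9 and higher in 1 of 16 (adjusted p = 0.000237), 3' end processing factors lower in 16 and higher in 7 of 32 (adjusted p = 0.0191), and zinc finger genes named ZNF lower in 250 and higher in 52 of 481 (adjusted p = 3.27e-07). Nuclear oxidative phosphorylation genes were higher in 26 and lower in 3 of 35 (adjusted p = 3.38e-07), and lymphoid markers higher in 5 and lower in 1 of 14 (adjusted p = 0.0327). With an estimated correlation 0 lists passed (smallest adjusted p = 0.644).

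Changed variations were also unevenly spread over the lists, with 12.9% of tested genes holding one. Within deciles of expression, 3 of 31 lists held more than other genes: SR proteins, hnRNPs and CLK kinases (22 of 39, Mantel-Haenszel odds ratio 6.92, 95% interval 3.6 to 13.3, adjusted p = 3.32e-10), zinc finger genes named ZNF (132 of 480, odds ratio 2.59, 95% interval 2.07 to 3.23, adjusted p = 1.04e-16) and DNA repair genes (15 of 36, odds ratio 2.73, 95% interval 1.4 to 5.34, adjusted p = 0.0238). Genes in a list are not independent replicates, and the number of exons per gene was not matched. The deciles used the mean over all 8 libraries. As DMSO 1 and 2 were relatively low in transcripts of low GC content, such genes can sit in too low a decile, and the effect of this on the odds ratios was not tested.

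Unannotated junctions gained use with SY-351 in most changed variations. If low read coverage were the cause, well covered genes would lack the shift, but in the genes with the highest CPM in SY-351, 1 of 3 groups of equal size, it was seen in 78.9% of 948 variations (95% Wilson interval 76.2 to 81.4%), against 84.5% in the group with the lowest. Among genes not lower in DMSO 1 and 2 the share was 81.1% of 1117 variations (95% Wilson interval 78.7 to 83.3%). This argues against the loss of whole transcripts of low GC content, since the genes were split by their totals. A loss of reads at junctions of low GC content within a gene was not tested and stays open. Whether DMSO 1 and 2 were among the authors' control samples is not known, and if they were left out their loss cannot have entered the table. The intervals cover counting error only, and the table gives no values per sample. An effect of SY-351 on junction use stays open as a hypothesis, and effects of the authors' junction filters were not tested.

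Transcripts running on past the end of a gene could raise a weakly expressed neighbour downstream. Among genes below 2 CPM in DMSO 3 and 4 with a gene of at least 10 CPM within 5 kb upstream, the mean log2 fold without DMSO 1 and 2 was 0.56 in 214 genes on the same strand and 0.38 in 170 on the opposite strand. The difference of 0.18 (95% bootstrap interval 0.01 to 0.36) gave p = 0.0518 (permutation test, two-sided, 100000 permutations), so these counts do not decide, and genes are not independent replicates.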
